A study of Homo sapiens with 34 samples.

How the data were processed

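Total RNA of 34 samples of the B-cell acute lymphoblastic leukemia lines Nalm6 (12 libraries), RS4:11 (11) and REH (11) was sequenced. Per the labels' protocols the cells grew in RPMI1640 medium with fetal bovine serum and received InO or a vehicle, RNA was extracted with a column kit, and libraries were made with a stranded Illumina kit for mRNA. Per the submitters' processing notes STAR version 2.6.0b and GATK were used, with the genome build GRCh38 (hg38). The counting program, the annotation release and the strand setting of the counting are not given in the sources used here, and GATK stands in the notes without a role. Antisense and overlapping genes can therefore not be told from their partners, and members of families of nearly identical genes, such as the histones, are uncertain where reads could be split between copies.

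The deposited table held expected counts per gene and library, estimated counts that need not be whole: 7.47% of all values and 19.7% of the values above 0 had decimals. They were rounded to whole numbers. Of 60754 rows, 92 were spike-in sequences that were 0 in each library and were removed, which left 60662 gene rows, 45 of them second copies of the pseudoautosomal genes. Small structural RNAs took 10.5 to 17% of the counts of a library, although the labels name an mRNA kit. Library totals ran from 34437574 to 83238137 counts with a median of 63794612. Intervals from counts and the floor used for groups at 0 (3 counts over the group) cover counting error only, since reads without molecular identifiers are not independent molecules. Between 98.2 and 98.4% of the tested genes had a position in the reference annotation (GENCODE, GRCh38), which was used for coordinates only, and histone genes and others with changed symbols were matched by gene identifier.

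Groups were cell line, genotype and treatment as the labels give them, with the replicate numbers of the labels' library names. In 2 groups with 2 libraries the titles carry other numbers than those names, which were kept. Chi-square values per gene between libraries of one group ran from 2.6 to 45.8, so no pair agreed within sampling noise and none was merged. The highest values, 31.5 and 45.8, involved RS4:11 WT InO replicate 3. The first principal component held 41.7% of the variance in Nalm6, 57.8% in RS4:11 and 52.1% in REH, and separated KO from WT libraries in each line. The second held 16.4, 10.6 and 16.2% and separated InO from control libraries. Whether equal replicate numbers mark shared cultures is not stated, and the numbers were not used in the design.

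The tests of the comparisons, the gene lists, the named-gene rule and the alternatives, apart from counting protein-coding genes only, were fixed before the data were examined. Tests of explanations and the simulation with equal responses were added later, and that simulation and the tests on CD22, on the ratio of the NF-kB to the p53 response and on myeloid genes were chosen after the results they bear on had been seen. Each line was fitted alone with edgeR 4.0.16 in R 4.3.3, using filterByExpr on its 4 groups, TMM factors, estimateDisp and glmQLFit with robust estimation, and glmQLFTest, two-sided. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The contrasts were InO against control in WT, InO against control in KO, the KO response minus the WT response (the interaction) and KO against WT in control. The filter kept 16252 genes in Nalm6, 17733 in RS4:11 and 18484 in REH, and the common biological coefficient of variation was 4.76, 6.67 and 4.16%. One fit of all 34 libraries in 12 groups, with 20536 genes, gave the mean of the interactions over the 3 lines and the differences between lines in the WT response. Standard errors are those of the log2 fold change implied by the fit.

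Gene lists were tested with camera of limma 3.58.1 on the edgeR counts with a preset correlation of 0.01, adjusted over 20 pathway lists and 12 contrasts of single lines, and within each contrast of the joint fit. A list needed 5 tested members. Camera compares the members with all other genes. With an estimated correlation 114 of 183 called lists kept an adjusted p under 0.05. Fry was the other alternative: its p tests whether a list's genes move, on balance, one way, and does not compare the list with other genes. The count of members past the threshold over all genes is given first, and the count adjusted over the list alone beside it. Lists of markers of other blood and tissue cells and of KMT2A-rearranged leukemia formed a family of their own. Of 207 list medians in comparisons of 2 groups 5 had a member at 0 counts in one group. With such members set to their bound 2 medians differed, that of the NF-kB list in RS4:11 control cells (-0.209, and -0.198 at the bound) and that of the myeloid list in REH KO with InO (0.216 and 0.344). Scores were the mean log2 CPM (TMM, prior count 2) of a list per library, for p53, E2F and G2/M genes and for the genes called in WT of both other lines, and were tested by exact two-sided permutation with adjustment over 45 tests.

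Genes were named by a fixed rule. It takes DNTT and CD22, the 5 genes with the largest rise and the 5 with the largest fall among called genes with a mean of at least 10 CPM in one group and libraries that do not overlap, with clone-based, immunoglobulin, T cell receptor and sex-linked control genes left out. It also takes up to 3 members of each called list in the list's main direction and 1 in the other, by smallest adjusted p. From the genes it takes, a selection was printed, and genes whose call or size rested on one library were mostly left out. The genes of the chromosome blocks and the genes shared by all lines were chosen after their values were seen.

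Alternatives were RLE factors in place of TMM, the Wald test of DESeq2 1.42.0, no filter beyond a count above 0, a stricter filter at a mean of 5 CPM, the replicate number as a block, only the 2 groups compared, all 34 libraries in one fit, each library left out in turn, a prior count of 0.5 for scores and an adjusted p of 0.01 for overlaps. Counting protein-coding genes only was added after the data had been seen. Windows of 10 Mb with at least 10 genes of at least 1 CPM were formed along the chromosomes and compared with shuffled gene positions.

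The edgeR steps were tested on counts simulated from the real means and library sizes with 200 changed genes. For Nalm6 InO against control in WT, over 16050 genes, 88.1% of the genes changed by 0.5, 98.5% of those changed by 1 and 98.5% of those changed by 2 on the log2 scale were called in the right direction. In RS4:11 (17409 genes) these shares were 77.6, 95.5 and 100%, and in REH (18129 genes) 86.6, 97 and 100%. For the interaction they were 71.6, 92.5 and 98.5% in Nalm6 over 16046 genes, 58.2, 82.1 and 97% in RS4:11 over 17387 genes and 71.6, 94 and 100% in REH over 18163 genes. The mean interaction over the lines recovered 88.1, 95.5 and 100% over 19337 genes. Unchanged genes called were 16, 10, 26, 8, 5, 15 and 9 in these simulations, taken by line with WT before interaction and the joint fit last. Levels of sex-linked control genes and a few results on single genes are not reported, and reads were not used here.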

Results

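RNA-seq counts per gene were available for 34 libraries of 3 human B-cell acute lymphoblastic leukemia cell lines. The lines were Nalm6, RS4:11, which carries the KMT2A-AFF1 fusion, and REH, which carries the ETV6-RUNX1 fusion. Each line was wild type (WT) or carried a knockout (KO) of DNTT, and received a vehicle as control or inotuzumab ozogamicin (InO), an antibody against the B-cell surface protein CD22 that carries the DNA-cleaving agent calicheamicin. The series title names DNTT as a regulator of the response to this drug, found in a CRISPR screen. The 12 groups held 3 libraries each, except RS4:11 KO with InO and REH WT control, which held 2. Total counts per library ran from 34437574 to 71993172 in Nalm6, from 47324124 to 79552463 in RS4:11 and from 58920592 to 83238137 in REH. The labels do not say whether libraries of one group came from separate cultures, so p-values measure the spread between these samples, which may be technical. Dose, exposure time and whether the KO cells were a clone or a pool are not given in the sources used here.

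DNTT encodes terminal deoxynucleotidyl transferase, which adds nucleotides without a template at the junctions of rearranging antigen receptor genes. The gene (ENSG00000107447.8) lies on chromosome 10 at 96304396 to 96338564, plus strand, in GRCh38. In control cells its mean level in CPM, the count scaled to the library total, was 115 ± 4.33 (SD, n = 3) in Nalm6 WT and 17 ± 0.482 (n = 3) in Nalm6 KO. In RS4:11 it was 19.6 ± 0.266 (n = 3) in WT, and the 3 KO control libraries held 0 to 3 counts. In REH it was 676 ± 44.9 (n = 2) in WT and 51.3 ± 3.83 (n = 3) in KO. The log2 difference between KO and WT was -2.76 (SE 0.04, edgeR adjusted p = 1.8e-18) in Nalm6 and -3.72 (SE 0.10, edgeR adjusted p = 2.3e-08) in REH. In RS4:11 the KO libraries held 5 counts in all against 3677 in WT, a log2 ratio of -9.33 with a counting interval of -10.96 to -8.11. The DNTT transcript was thus lower in KO than in WT in each line, and the Nalm6 KO control libraries still held 1120 to 1241 counts of it. InO exposure raised DNTT by 0.17 (SE 0.04, edgeR adjusted p = 2.3e-03) in Nalm6 WT and by 0.23 (SE 0.05, edgeR adjusted p = 3.0e-03) in Nalm6 KO on the log2 scale. Both calls were lost when all 34 libraries were fitted together (adjusted p = 5.49e-02 and 5.42e-02).

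CD22, the cell surface target of InO (ENSG00000012124.17, chromosome 19 at 35319261 to 35347355, plus strand), was measured at similar levels in both genotypes. Control WT and KO cells held 56.4 and 57.2 CPM in Nalm6, 100 and 96.5 CPM in RS4:11, and 153 and 149 CPM in REH. The 95% intervals of the log2 difference between KO and WT reached from -0.073 to 0.109, from -0.157 to 0.053 and from -0.107 to 0.036, and no adjusted p was below 4.6e-01 in edgeR's quasi-likelihood test. With InO, CD22 rose in REH by 0.31 (SE 0.04, edgeR adjusted p = 5.2e-07) in WT and by 0.16 (SE 0.03, edgeR adjusted p = 1.6e-03) in KO. In RS4:11 WT CD22 fell by 0.18 (SE 0.05, edgeR adjusted p = 2.4e-02), a call that was lost without WT control replicate 3 (adjusted p = 9.93e-02) and without WT InO replicate 2 (7.11e-02) or 3 (5.15e-02).

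**Figure D1:**
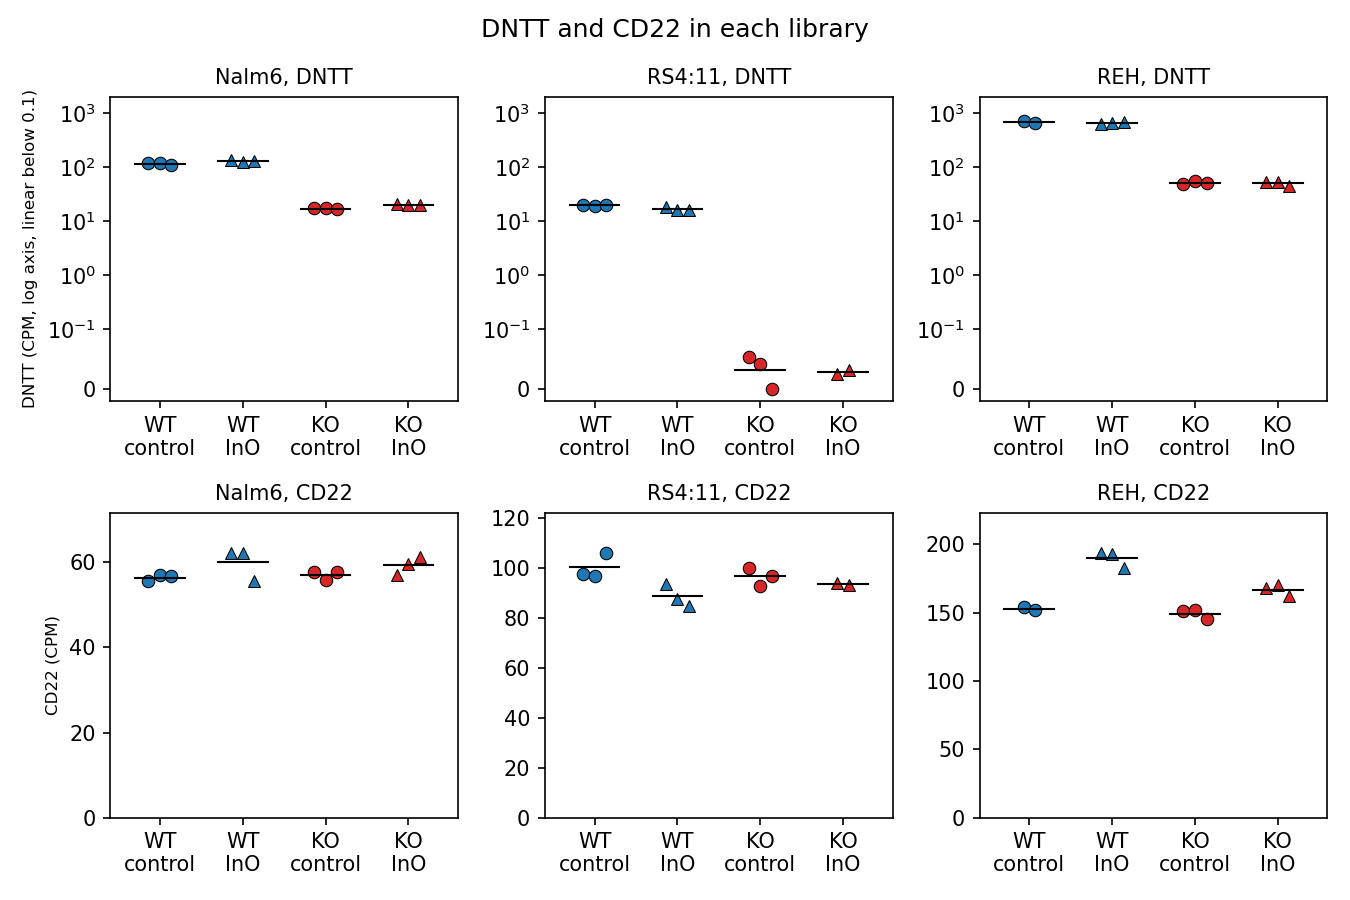
Levels of DNTT (upper, CPM on a log axis that is linear below 0.1) and CD22 (lower, CPM) in each library, by line, genotype and treatment. Circles are control and triangles InO libraries, blue WT and red KO, and the black bar is the group mean, which for DNTT was 115 in Nalm6 WT control and 17 in Nalm6 KO control.

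The first question was which genes responded to InO in WT cells. In Nalm6 WT the p53 targets led the response. BBC3, which encodes the pro-apoptotic protein PUMA, rose by 3.50 on the log2 scale (SE 0.08, edgeR adjusted p = 2.3e-16), and CDKN1A, the cyclin-dependent kinase inhibitor p21, rose by 3.05 (SE 0.04, edgeR adjusted p = 6.2e-19). TP53INP1 rose by 2.94, ZMAT3 by 2.43 and SESN1, a sestrin that restrains growth signalling, by 2.28. The death receptor gene TNFRSF10B rose by 1.79 and the pore-forming BAX by 1.09. Of 34 measured p53 target genes 32 rose, with 33 adjusted over the list alone, and the median change was 0.92 (camera adjusted p = 1.76e-246). Histone genes moved the other way: 22 of 23 fell, all 23 adjusted over the list alone, with a median of -0.93 (camera adjusted p = 1.23e-91), among them HIST1H2BB at -1.26, HIST1H4D at -1.15 and HIST1H2BM at -1.09. The copies of these genes are nearly identical, so single histone genes are uncertain where the counting could split reads between them. Of 40 DNA replication and E2F target genes 35 fell, 37 adjusted over the list alone, with a median of -0.27 (camera adjusted p = 6.19e-26), including RRM2, the small subunit of ribonucleotide reductase, at -0.62, the flap endonuclease FEN1 at -0.46 and the helicase subunit MCM4 at -0.35.

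Smaller shifts were seen in other groups of Nalm6 WT cells. In the unfolded protein and integrated stress response list 14 of 25 genes fell, among them ASNS (-0.68), PHGDH (-0.61) and PSAT1 (-0.49), which serve asparagine and serine synthesis, while DDIT4 rose by 0.62 (camera adjusted p = 7.32e-03 with an estimated correlation). In the ribosome biogenesis and MYC target list 18 of 30 genes fell, 21 adjusted over the list alone, including NCL (-0.23) and LYAR (-0.27), with adjusted p = 3.53e-02 with an estimated correlation. Interferon-stimulated genes rose in 15 of 31 cases, 18 adjusted over the list alone, among them STAT2 (0.70) and IFIT3 (0.42), and precursor B cell genes in 18 of 31, among them CD38 (0.63), BLNK (0.42) and RAG1 (0.40). Both calls held with an estimated correlation, at adjusted p = 6.44e-03 and 2.47e-02. Of 40 G2/M genes 31 fell, such as KIF20A (-0.38) and AURKB (-0.36), and of 28 homologous recombination genes 18 fell, such as EXO1 (-0.39) and FANCI (-0.32). With an estimated correlation these lists had adjusted p = 6.61e-02 and 1.46e-01. NF-kB and inflammatory genes rose in 9 of 16 cases, led by RELB at 0.85 (adjusted p = 2.45e-01 with an estimated correlation). Pro-apoptotic BCL2 family and death receptor genes rose in 9 of 18 cases and fell in 2 (camera adjusted p = 9.90e-05 with an estimated correlation). That list shares BAX, BBC3, FAS and TNFRSF10B with the p53 list, so its call is not separate from that of the p53 targets. Its median was 0.152 and its mean 0.579. Damage signalling kinases and mediators fell in 9 of 20, such as H2AFX at -0.63 and CLSPN by -0.48, while ATM rose by 0.17 (camera adjusted p = 3.53e-02 with an estimated correlation). The cholesterol biosynthesis, glycolysis and hypoxia, heat shock and immediate early, and senescence and lymphoid activation lists passed with camera's preset correlation. With an estimated correlation they had adjusted p = 6.11e-02, 1.84e-01, 9.64e-02 and 2.79e-01. Camera did not call the anti-apoptotic (adjusted p = 6.04e-01), non-homologous end joining (2.38e-01), glutathione metabolism and drug efflux (1.04e-01) and lysosome (3.55e-01) lists. In all, 4695 of 16252 tested genes passed an adjusted p of 0.05, 2512 higher and 2183 lower, and 316 of them changed at least 2-fold.

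In RS4:11 WT both p53 targets and NF-kB genes rose. BIRC3, an inhibitor of apoptosis that NF-kB induces, rose by 4.18 (SE 0.15, edgeR adjusted p = 1.1e-10), and the cytidine deaminase gene APOBEC3H by 3.38 (SE 0.09, edgeR adjusted p = 6.8e-12). PHLDA3, a repressor of AKT, rose by 3.08. Of 37 p53 targets 33 rose, also 33 adjusted over the list alone, where 1 fell, with a median of 1.05 (camera adjusted p = 4.59e-240), including BBC3 (2.01), CDKN1A (1.80) and BAX (1.61). Of 20 NF-kB and inflammatory genes 16 rose, also 16 adjusted over the list alone, with a median of 0.89 (camera adjusted p = 2.71e-80), including TNFAIP3 (2.11) and RELB (1.93). Surface genes of the senescence and lymphoid activation list rose in 14 of 21 cases, among them HLA-DQB1 (0.73) and HLA-B (0.62), and heat shock and immediate early genes in 13 of 24, among them IER5 (1.68) and JUN (1.64). Of 40 E2F targets 36 fell, with a median of -0.36 (camera adjusted p = 2.01e-42), including RRM2 (-0.62) and MCM4 (-0.49). CLSPN, which is not on that list, fell by 0.75. Cyclin E2, CCNE2, fell by 1.04. Of 24 histone genes 22 fell, with a median of -0.51, and 19 of 28 homologous recombination genes fell, such as BRIP1 (-0.67) and RAD51AP1 (-0.59). These 7 lists kept an adjusted p of at most 1.01e-02 with an estimated correlation. The G2/M list did not pass (camera adjusted p = 5.36e-01): 9 of 40 members rose, such as UBE2C by 0.51 and CCNB1 by 0.37, and 4 fell, such as CENPE at -0.23.

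The ribosome biogenesis and MYC target list rose in RS4:11 WT, in 15 of 30 members, including PPAN (0.31) and RRP12 (0.30), with adjusted p = 3.83e-02 with an estimated correlation. Precursor B cell genes fell in 11 of 31 cases, among them the surrogate light chain gene IGLL1 (-0.68), VPREB3 (-0.64) and RAG1 (-0.40), and rose in 2 cases, 1 of them IKZF3 (0.61). That call was lost with an estimated correlation (adjusted p = 2.19e-01). In the unfolded protein and integrated stress response list the median was -0.01 while the mean was 0.12 and camera's direction was up (camera adjusted p = 4.30e-02, adjusted p = 2.99e-01 with an estimated correlation). RS4:11 WT InO replicate 3 stood apart from the other libraries of its group. In all, 2971 of 17733 genes passed, 1393 higher and 1578 lower, with 222 changed at least 2-fold, and 2903 passed without that replicate.

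REH WT had the most genes past the threshold, 6901 of 18484, with 3504 higher, 3397 lower and 521 changed at least 2-fold. APOBEC3H rose by 4.98 (SE 0.12, edgeR adjusted p = 1.6e-17) and PURPL, a long noncoding RNA, by 4.83 (SE 0.06, edgeR adjusted p = 1.5e-21). PHLDA3 rose by 4.09, BBC3 by 3.03, the death receptor gene FAS by 2.95 and TRIM22 by 2.49. All 37 measured p53 targets rose, with a median of 1.53 (camera adjusted p = 4.57e-296), and all 37 passed when adjusted over the list alone. Of 24 histone genes 23 fell, all 24 adjusted over the list alone, with a median of -1.19, led by HIST1H1T (-2.24), HIST1H2AD (-1.80) and HIST1H3J (-1.66). Of 40 E2F targets 38 fell and 1, PCNA, rose by 0.24, with 39 lower adjusted over the list alone and a median of -0.32 (camera adjusted p = 1.02e-25). E2F8 fell by 0.88, E2F2 by 0.66 and RRM2 by 0.64. Ribosome biogenesis and MYC target genes fell in 21 of 30 cases, 24 adjusted over the list alone, such as ODC1 (-0.36), NOLC1 (-0.33) and MYC (-0.28), and glycolysis and hypoxia genes in 21 of 26, such as PGAM1 (-0.30) and ENO1 (-0.30). Both held with an estimated correlation, at adjusted p = 4.48e-03 and 4.18e-02. Interferon-stimulated genes rose in 18 of 34 cases, such as IFIT2 (0.73) and HERC5 (0.71), with adjusted p = 4.18e-02 with an estimated correlation. In the stress response list 13 of 25 genes fell, including CHAC1 (-1.29) and ASNS (-0.76), while ATF3 rose by 1.12 (adjusted p = 2.37e-02 with an estimated correlation). Of 20 NF-kB genes 7 rose, and 1 fell (adjusted p = 2.79e-01 with an estimated correlation). Myeloid markers rose in 4 of 8 cases, among them ITGAM by 1.83, and the list was not called with an estimated correlation (adjusted p = 3.26e-01).

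Genes past the threshold in the same direction were counted across the 3 WT lines, whose comparisons share no library. Of 14734 genes tested in each line 364 rose in all 3, where independent lists would share 37.1, and 472 fell in all 3, against 45 for independent lists. The size of the response differed between lines by a test of the difference itself. NF-kB genes responded more in RS4:11 than in Nalm6, with a median difference of 0.69 over 23 genes (camera adjusted p = 9.18e-05 with an estimated correlation), including NFKB2 (1.76) and TNFAIP3 (1.73). REH lay below RS4:11 for this list by a median of -0.72, with BIRC3 at -3.90 and RELB at -1.87 (camera adjusted p = 3.34e-06 with an estimated correlation). The p53 targets responded more in REH than in Nalm6, by a median of 0.45 with 20 of 38 genes higher, among them AEN (0.88) and RRM2B (0.88), and more in REH than in RS4:11, by a median of 0.52 with 29 of 38 higher, among them SESN1 (1.29). In RS4:11 against Nalm6 the median was -0.12, with 12 genes lower, such as CDKN1A (-1.24) and BBC3 (-1.48), and 8 higher, such as TNFRSF10B (0.82). With an estimated correlation the camera adjusted p of these p53 list differences was 3.57e-10, 6.85e-10 and 3.91e-02. Ribosome biogenesis genes, which fell in Nalm6 and REH WT and rose in RS4:11 WT, were higher in RS4:11 than in Nalm6 in 26 of 30 cases, including RRP12 (0.47). The heat shock and immediate early list had a median of 0.20 and a mean of -0.21 in that comparison (camera adjusted p = 1.29e-02, adjusted p = 7.80e-02 with an estimated correlation). In all, 3177 of 20536 genes differed between RS4:11 and Nalm6, 1113 between REH and Nalm6 and 4059 between REH and RS4:11. Between REH and Nalm6 569 were higher and 544 lower in REH, against 519 and 1098 without a filter on low counts. The REH and Nalm6 count fell to 493 without REH WT control replicate 3, 584 without REH WT control replicate 2, 697 without Nalm6 WT InO replicate 2 and 729 without REH WT InO replicate 3. The REH and RS4:11 count fell to 2660 without REH WT control replicate 3. The REH libraries carry another run of library numbers than the rest, so line and a possible batch cannot be told apart in the comparisons with REH.

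**Figure D2:**
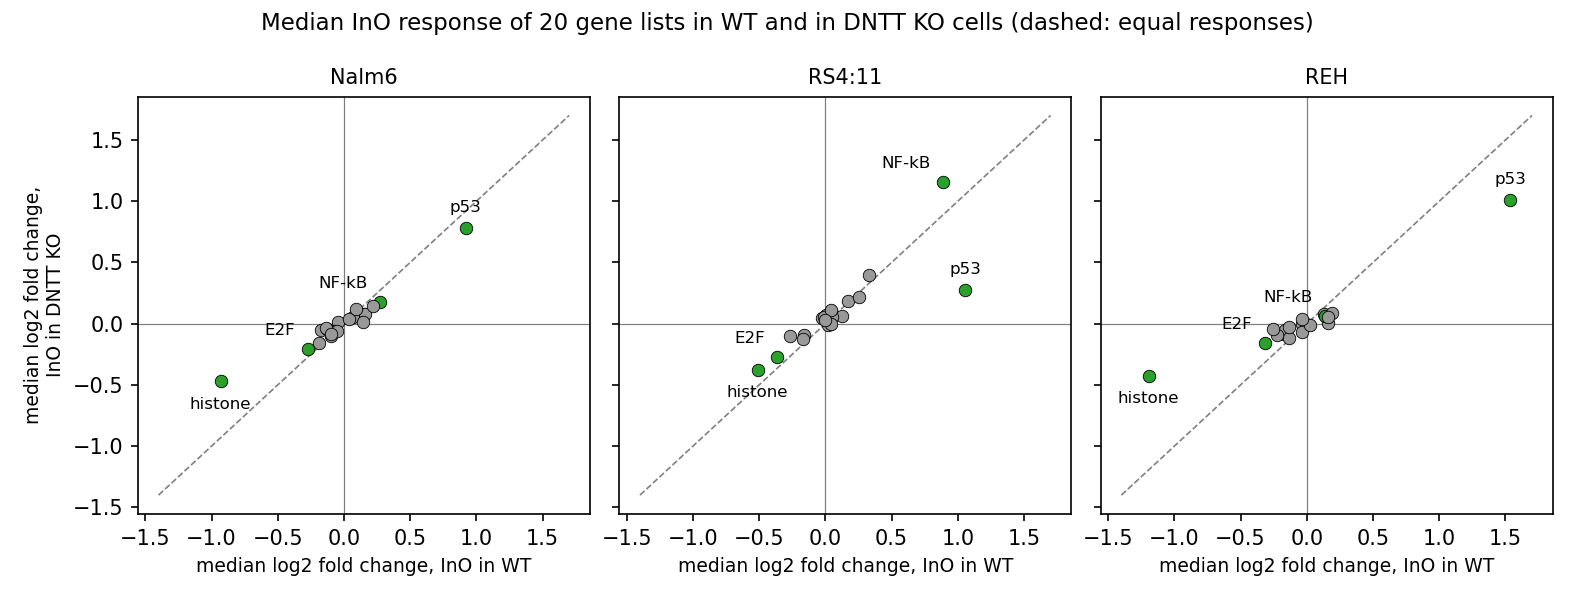
Median log2 fold change with InO of each of the 20 gene lists in WT cells (horizontal) and in DNTT KO cells (vertical), by line, with green points for the p53, histone, E2F and NF-kB lists and a dashed line where both responses are equal. The p53 point lies at 0.92 and 0.78 in Nalm6, at 1.05 and 0.27 in RS4:11 and at 1.53 and 1.01 in REH.

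In DNTT KO cells InO raised p53 targets and lowered histone and E2F genes in each line. In Nalm6 KO 29 of 34 p53 targets rose, 30 adjusted over the list alone, with a median of 0.78 (camera adjusted p = 1.17e-08 with an estimated correlation). CDKN1A rose by 2.65 (SE 0.04, edgeR adjusted p = 7.1e-18), BBC3 by 2.58 and TP53INP1 by 1.69, and 22 of 23 histone genes fell with a median of -0.47 (camera adjusted p = 2.10e-02 with an estimated correlation). Of 40 E2F targets 36 fell, among them RRM2 (-0.39), with adjusted p = 1.06e-03 with an estimated correlation. In RS4:11 KO 17 of 37 p53 targets rose and 2 fell, with 18 and 3 adjusted over the list alone and a median of 0.27 (camera adjusted p = 3.80e-05 with an estimated correlation). TNFRSF10B rose by 1.85 there, BBC3 by 0.88, BAX by 0.73 and CDKN1A by 0.61, while PIDD1, a p53-induced death domain protein, fell by 0.36. Of 24 histone genes 15 fell, 20 adjusted over the list alone, with a median of -0.38 (camera adjusted p = 1.54e-02 with an estimated correlation). Of 40 E2F targets 29 fell and 1 rose, with 35 lower and 1 higher adjusted over the list alone and a median of -0.27 (camera adjusted p = 9.68e-04 with an estimated correlation). The NF-kB list had the larger median, 1.16, with 14 of 20 genes higher and 16 adjusted over the list alone (camera adjusted p = 5.05e-07 with an estimated correlation). BIRC3 rose by 4.16, TNFAIP3 by 2.65, RELB by 2.29 and NFKB2 by 2.17. In REH KO 35 of 37 p53 targets rose, also 35 adjusted over the list alone, with a median of 1.01 (camera adjusted p = 1.17e-08 with an estimated correlation), including PHLDA3 (3.89), BBC3 (2.40) and FAS (1.75). PURPL, which is not on that list, rose by 3.89. Histone genes fell in 22 of 24 cases, with a median of -0.43, and E2F targets fell in 29 of 40 cases and rose in 1 (camera adjusted p = 1.94e-03 and 1.81e-03 with an estimated correlation).

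Fewer genes passed the threshold in KO than in WT cells. In Nalm6 KO 1621 genes passed, 911 higher and 710 lower, of which 1359 were also called in WT in the same direction. In RS4:11 KO 1241 passed, 601 higher and 640 lower, with 909 shared with WT, and in REH KO 2253 passed, 1133 higher and 1120 lower, with 2106 shared. Independent lists would share 140.8 higher and 95.37 lower genes in Nalm6, 47.21 and 56.95 in RS4:11, and 214.8 and 205.8 in REH, and WT and KO comparisons have no library in common. RS4:11 KO with InO had 2 libraries, and simulated equal responses also gave fewer calls there, 1719 to 1799 in KO against 2356 to 2433 in WT, whereas in Nalm6 they gave 3331 to 3420 against 3135 to 3290 and in REH 5468 to 5612 against 4637 to 4703. With only the 2 groups fitted RS4:11 gave 1839 genes in KO and 2069 in WT, and with all 34 libraries in one fit 2045 in RS4:11 KO and 1242 in REH KO. Without a filter on low counts the balance turned, to 923 higher and 1140 lower in Nalm6 KO, 987 and 683 in RS4:11 KO and 1153 and 1436 in REH KO. Single libraries moved these counts. Nalm6 KO gave 1057 and 1075 genes without KO control replicate 1 or 2, and 1079 without KO InO replicate 2 or 3. RS4:11 KO gave 401 without KO InO replicate 1, 431 without KO InO replicate 3, and 769 and 730 without KO control replicates 2 and 3. REH KO gave 1409 without KO control replicate 1. Of 14734 genes tested in each line 49 rose and 141 fell in all 6 comparisons of InO with control.

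The central comparison was whether the InO response differed between DNTT KO and WT cells. The p53 targets rose less in KO cells in each line. In Nalm6 the KO response minus the WT response was lower for 13 of 34 p53 targets and higher for none, 18 lower adjusted over the list alone, with a median of -0.21 (camera adjusted p = 8.39e-34, and 1.53e-05 with an estimated correlation). TP53INP1 differed by -1.25 (SE 0.09, edgeR adjusted p = 4.1e-07), BBC3 by -0.92 (SE 0.11, edgeR adjusted p = 1.9e-04), the antiproliferative BTG2 by -0.65, TNFRSF10B by -0.51 and TRIM22 by -0.48. TP53INP1 and BTG2 were already higher in KO than in WT without drug, so their difference in response lies largely in the control level. The histone list was higher, meaning that it fell less in KO: 15 of 23 genes passed, 22 adjusted over the list alone, with a median of 0.43 (camera adjusted p = 1.69e-02 with an estimated correlation), such as HIST1H2BB (0.70), HIST1H4D (0.57) and HIST1H2BM (0.55). HIST1H4D was not called when all 34 libraries were fitted together (adjusted p = 7.66e-02). Of 40 G2/M genes 3 passed and 17 did when adjusted over the list alone, such as KIF20A (0.29), with a median of 0.12 (camera adjusted p = 4.92e-02 with an estimated correlation). Immediate early genes JUN (-0.84) and DUSP1 (-0.40) were lower, and their list was not called with an estimated correlation (adjusted p = 5.69e-02). The interferon list was lower by a median of -0.14, with STAT2 at -0.43 as the member that passed over all genes. In all, 224 genes passed, 83 higher and 141 lower, 2481 at an unadjusted p under 0.05. Among the genes called in WT, the interaction had the opposite sign to the WT response in 93.8%. Both contrasts use the WT libraries, and simulated equal responses gave 69.1 to 70.4% over 5 runs. The simulation drew each gene independently and so held no shift shared by the libraries of a group. DESeq2 called 486 genes, 53.3% of them higher against 37.1% here, and 667 were called without a filter on low counts. The count was 124, 115 and 751 without WT InO replicate 1, 2 or 3, and 133 and 131 without KO InO replicate 2 or 3.

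In RS4:11 the difference in p53 targets was larger. The KO response was below the WT response for 27 of 37 p53 targets, and adjusted over the list alone 32 were lower and 1 higher, with a median of -0.76 (camera adjusted p = 1.69e-160, and 3.65e-07 with an estimated correlation). Outside that list APOBEC3H differed by -2.62 (SE 0.17, edgeR adjusted p = 1.5e-06), and on it FAS by -1.91 (SE 0.17, edgeR adjusted p = 3.7e-05) and CDKN1A by -1.19 (SE 0.06, edgeR adjusted p = 1.1e-07). FDXR, a mitochondrial electron transfer protein, differed by -1.76, BBC3 by -1.13, MDM2, a ubiquitin ligase, by -0.98 and BAX by -0.88. The NF-kB list differed in the other direction, with a median of 0.11 (camera adjusted p = 2.43e-02 with an estimated correlation). Of its 20 members 2 passed over all genes, and 4 adjusted over the list alone. Of 21 genes of the senescence and lymphoid activation list CD69 (2.92) and HLA-DQA1 (1.48) passed, and 2 were higher and 2 lower adjusted over the list alone. Without drug CD69 and HLA-DQA1 lay lower in KO than in WT by more than these differences in response. Both thus stayed lower in KO than in WT with InO. The list's median was 0.015, and -0.007 with protein-coding genes only, and its call was lost with an estimated correlation (adjusted p = 1.05e-01). The E2F target list had a median of 0.13 (camera adjusted p = 2.77e-02 with an estimated correlation), although 0 of its 40 members passed in edgeR over all genes, and 4 were higher and 1 lower adjusted over the list alone. The homologous recombination list had a median of 0.12 (camera adjusted p = 3.53e-02 with an estimated correlation), with 1 of 28 members higher over all genes and 9 adjusted over the list alone. The histone list had a median of 0.16, and the call was lost with an estimated correlation (adjusted p = 1.79e-01). In all, 103 genes passed, 18 higher and 85 lower, 1858 at an unadjusted p under 0.05. The interaction had the opposite sign to the WT response in 84.5% of the genes called in WT, where simulated equal responses gave 68.2 to 70.3%. DESeq2 called 182 genes, 30.2% of them higher against 17.5% here, while 723 were called without a filter on low counts, 55.2% of them higher, and 343 with all 34 libraries in one fit, 44.9% of them higher. The count was 68 without WT control replicate 2 or without KO control replicate 3, 158 without WT InO replicate 3, and 67 and 51 without KO InO replicate 1 or 3, where 1 library remains in that group.

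In REH the response of the p53 targets was lower in KO for 28 of 37 genes, 30 adjusted over the list alone, with a median of -0.49 (camera adjusted p = 3.36e-68, and 3.00e-05 with an estimated correlation). FAS differed by -1.20 (SE 0.09, edgeR adjusted p = 2.6e-08), BTG2 by -0.92 (SE 0.06, edgeR adjusted p = 3.9e-09), TRIM22 by -0.71 and TNFRSF10B by -0.55. Histone genes fell less in KO in 22 of 24 cases, 23 adjusted over the list alone, with a median of 0.76 (camera adjusted p = 1.16e-04 with an estimated correlation), such as HIST1H1T (1.44) and HIST1H3J (1.12). E2F targets fell less in 19 of 40 cases, 35 adjusted over the list alone, with a median of 0.17 (camera adjusted p = 1.03e-03 with an estimated correlation), including E2F8 (0.51), E2F2 (0.42) and RRM2 (0.38). Glycolysis and hypoxia genes were higher in 14 of 26 cases, such as PFKFB4 (0.43) and ALDOC (0.34), and ribosome biogenesis genes in 7 of 30, both called with an estimated correlation (adjusted p = 1.81e-02 and 6.52e-03). In all, 1260 genes passed, 599 higher and 661 lower, 3819 at an unadjusted p under 0.05. The interaction had the opposite sign to the WT response in 97.9% of the genes called in WT, where simulated equal responses gave 66.4 to 68.1%. The count was 594 with all 34 libraries in one fit, 717 and 501 without WT control replicate 2 or 3, 829 without KO InO replicate 1 and 2228 without KO InO replicate 3.

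Averaged over the 3 lines in one fit, 30 of 38 p53 targets responded less in KO, 32 adjusted over the list alone, with a median of -0.53 (camera adjusted p = 2.65e-16 with an estimated correlation). MDM2 differed by -0.61 (SE 0.03, edgeR adjusted p = 3.6e-17), TRIM22 by -0.71 (SE 0.03, edgeR adjusted p = 2.5e-17) and BTG2 by -0.74. Of 24 histone genes 22 were higher, such as HIST1H3J (0.65), and of 40 E2F targets 23 were, such as E2F8 (0.32). CLSPN, of the damage signalling list, was higher by 0.29. Here 964 of 20536 genes passed, 461 higher and 503 lower. The balance turned with RLE factors (511 higher and 473 lower), with DESeq2 (746 and 591) and with protein-coding genes only (578 and 514). It leaned further to lower genes without a filter on low counts (372 and 594) and at a mean of at least 5 CPM (478 and 726). Of 14734 genes tested in each line none was called higher in all 3 interactions, where independent lists would share 0.00268, and 17 were called lower, where they would share 0.0276. Among these were the listed p53 targets FDXR, BTG2, SESN1, TRIM22, TNFRSF10B, MDM2 and DDB2. The ratio of the mean KO response to the mean WT response of the p53 list was 0.769 in Nalm6, 0.326 in RS4:11 and 0.729 in REH. The score of the list, its mean log2 CPM, rose by 1.20 in WT and 0.92 in KO in Nalm6, by 1.22 and 0.42 in RS4:11, and by 1.72 and 1.24 in REH, with SDs between libraries of a group of 0.008 to 0.023. The difference between these responses was -0.28 in Nalm6 (two-sided exact permutation p = 0.005, 0.045 adjusted over 45 scores), the smallest that its 400 assignments allow. It was -0.80 in RS4:11 (exact permutation p = 0.26, adjusted 0.285) and -0.47 in REH (exact permutation p = 0.095, adjusted 0.129). In both lines assignments that exchange control libraries alone keep the difference between the genotypes with InO, which was larger in size than the difference between the responses. In Nalm6 the KO score lay above WT in control (4.585 and 4.537) and below it with InO (5.509 and 5.74). The permutation exchanges genotype labels within each treatment, so it asks whether the genotypes differ at all. The p of 0.005 in Nalm6 is therefore not a test of equal responses. For InO against control the smallest exact permutation p was 0.1.

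**Figure D3:**
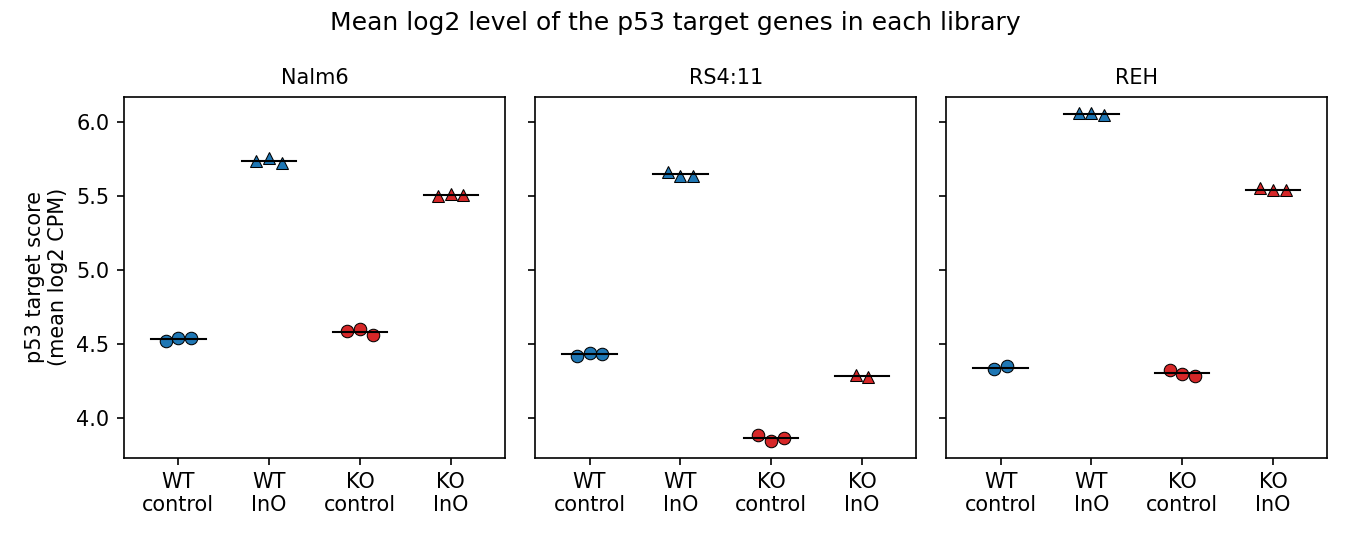
Mean log2 CPM of the measured p53 target genes in each library, by line, genotype and treatment. Circles are control and triangles InO libraries, blue WT and red KO, with group means as black bars, and the InO minus control difference is 1.22 in RS4:11 WT and 0.42 in RS4:11 KO.

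DNTT KO and WT cells were also compared without drug. In Nalm6 KO control cells the surface integrin chain ITGB2 differed by -4.87 (SE 0.14, edgeR adjusted p = 1.3e-14) and the antisense transcript TP73-AS1 by -3.86, and the strand setting of the counting is not given in the sources used here, so it cannot be told from its overlapping partner. IRAK3, a regulator of innate immune signalling, had 0 counts in KO against 4837 in WT, at least 2100-fold lower with a floor of 3 counts over the group, and ASRGL1 had 0 against 1638, at least 709-fold lower. NEURL1B was higher by 2.16 and DEPP1 by 2.01. Cholesterol biosynthesis genes were lower in 20 of 23 cases, with a median of -0.37 (camera adjusted p = 2.14e-04 with an estimated correlation), including HMGCS1 (-0.81) and LSS (-0.78). Ribosome biogenesis genes were lower in 26 of 30 cases, 28 adjusted over the list alone, such as LYAR (-0.37) and RRP12 (-0.36), with adjusted p = 1.63e-02 with an estimated correlation. The p53 target list was not called (camera adjusted p = 1.93e-01), with 11 genes higher, such as TP53INP1 (1.05) and BTG2 (0.79), and 9 lower, such as BAX (-0.86). In all, 5962 genes differed, 2898 higher and 3064 lower in KO.

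In RS4:11 KO control cells 23 of 37 p53 targets were lower and 2 higher, with a median of -0.26 (camera adjusted p = 2.06e-03 with an estimated correlation). PHLDA3 differed by -3.33 (SE 0.16, edgeR adjusted p = 7.7e-10), DRAM1 by -1.53 and TNFRSF10B by -1.29, and TP53INP1 had 3 counts in KO against 452, a log2 ratio of -7.05 with a counting interval of -9.33 to -5.49. Surface genes of the senescence and lymphoid activation list were lower in 14 of 21 cases, with a median of -0.60, including CD69 (-3.86), HLA-DQA1 (-3.24), CD70 (-1.63) and HLA-DPB1 (-1.08). DYNC1I1 was higher by 5.26 and SLC25A13 by 2.83, while TES had 0 counts against 5309, at least 1550-fold lower. In all, 5640 genes differed, 2621 higher and 3019 lower.

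Part of the difference between KO and WT control cells followed position along the genome. In Nalm6 the 140 measured genes of chromosome 21 had a median of -0.41, with 94 called lower and 4 higher in KO, while all other genes had a median near 0 (-0.003). In RS4:11 the 151 measured genes of the first 50 Mb of chromosome 8 had a median of 0.88, with 134 called higher and 3 lower, against 0.002 for all other genes. In windows of 10 Mb with at least 10 genes the median lay 0.3 or more from 0 in 3 of 285 windows in Nalm6, 9 of 287 in RS4:11 and 0 of 288 in REH. Shuffled gene positions gave at most 1, 1 and 0 such windows.

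**Figure D4:**
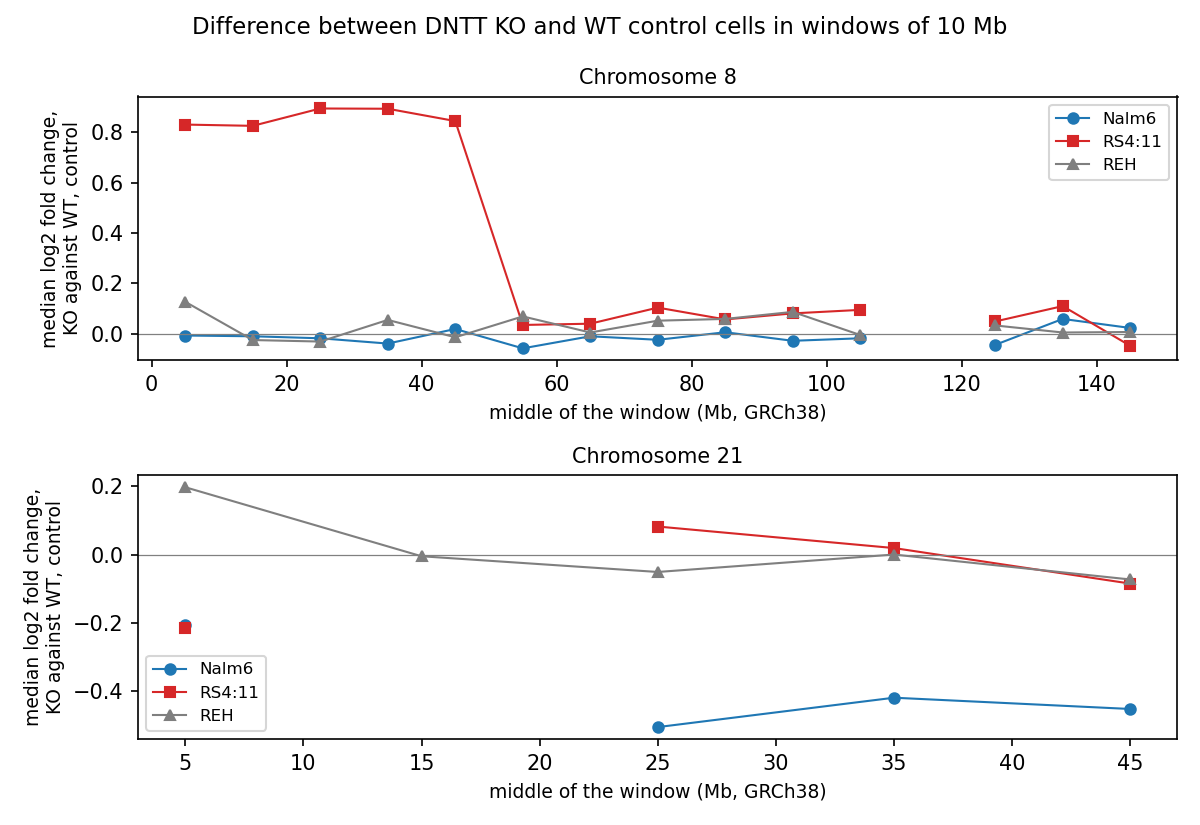
Median log2 fold change between DNTT KO and WT control cells in windows of 10 Mb along chromosomes 8 and 21 (position in Mb, GRCh38), by line, with gaps where a window held fewer than 10 genes. RS4:11 lies above 0.8 over the first 50 Mb of chromosome 8, and Nalm6 lies below 0 in each drawn window of chromosome 21.

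In REH KO control cells the unfolded protein and integrated stress response list was higher in 16 of 25 cases, such as DNAJB9 (0.56), TRIB3 (0.44) and PDIA4 (0.34), with adjusted p = 1.69e-02 with an estimated correlation. The senescence and lymphoid activation list was higher in 13 of 19, with HLA-DPB1 (0.85), HLA-DPA1 (0.61) and HLA-DRA (0.55), whereas CD69 differed by -2.88. SUCNR1, the succinate receptor, was higher by 3.43 (SE 0.07, edgeR adjusted p = 6.1e-19), and IFITM3, an interferon-induced restriction factor, differed by -7.36 (SE 0.13, edgeR adjusted p = 2.6e-19). In all, 4814 genes differed, 2466 higher and 2348 lower, and 2993 did without WT control replicate 3. Over the 3 lines 112 genes were higher and 123 lower in KO in each, where independent lists would share 55.9 and 55.2. Those lower in each included DNTT, ITGB2, MX2, LGALS1 and S100A4, and those higher DDR1. ITGB2 lies on chromosome 21, most of whose measured genes lay lower in Nalm6 KO. Where a line has 1 KO clone or pool, genotype and clone cannot be told apart in these comparisons.

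Lists of markers of other cell types were tested in the same way. The plasma and mature B cell list had 4 of 11 members higher in Nalm6 WT with InO, such as TNFRSF13C (0.46), and was not called (camera adjusted p = 2.89e-01). It passed in RS4:11 KO (median -0.161) and REH KO (median 0.131) with InO, and both calls were lost with an estimated correlation (adjusted p = 2.24e-01 in each). The myeloid list passed in REH KO with InO and in the RS4:11 interaction, and was lost likewise (adjusted p = 3.28e-01 and 3.58e-01). T and NK cell markers were testable in REH, with 1 of 5 members higher in WT with InO (camera adjusted p = 5.62e-01). In REH KO control cells 3 of the 5, CD4, NKG7 and TRAT1, were lower than in WT, with a list median of -0.97 (camera adjusted p = 3.42e-01), and CD4 and TRAT1 stood below 1 CPM in both genotypes. Epithelial and stromal markers were testable in the fit over all lines, with camera adjusted p = 6.77e-01 for the interaction. Fewer than 5 erythroid and megakaryocyte markers passed the expression filter. In RS4:11, 10 genes typical of KMT2A-rearranged leukemia were measured, and 2 rose and 1 fell with InO in WT (camera adjusted p = 8.01e-01).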

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

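The tests on CD22, on the ratio of the NF-kB to the p53 response and on myeloid genes, and the simulation with equal responses, were chosen after the results they bear on had been seen. The results collected here are differences in the InO response between DNTT KO and WT cells of a line, or between WT cells of different lines, that passed a test of the difference itself. Lists are those that passed camera with the preset and with the estimated correlation. The pro-apoptotic list shares BAX, BBC3, FAS and TNFRSF10B with the p53 list, so its calls are not separate from those of the p53 targets.

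In Nalm6 224 genes differed in response between KO and WT. The median log2 difference, KO response minus WT response, was 0.43 for histone genes, -0.215 for p53 targets, -0.145 for interferon-stimulated genes, 0.121 for G2/M genes, 0.115 for ribosome biogenesis genes, 0.097 for the stress response list and -0.05 for the pro-apoptotic list. In RS4:11 103 genes differed, with medians of -0.757 for p53 targets, 0.127 for E2F targets, 0.122 for homologous recombination genes, 0.118 for damage signalling genes, 0.113 for NF-kB genes and -0.023 for the pro-apoptotic list. In REH 1260 genes differed. There the medians were 0.762 for histone genes, -0.487 for p53 targets, 0.193 for glycolysis and hypoxia genes, 0.169 for E2F targets, 0.135 for ribosome biogenesis genes, -0.133 for the pro-apoptotic list, -0.121 for interferon-stimulated genes, 0.117 for damage signalling genes and 0.115 for cholesterol biosynthesis genes.

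The mean difference over the 3 lines was called for 964 genes. Its medians were -0.532 for p53 targets, 0.444 for histone genes, -0.133 for heat shock and immediate early genes, 0.122 for E2F targets, -0.11 for interferon-stimulated genes, -0.092 for the pro-apoptotic list, 0.092 for damage signalling genes, 0.086 for homologous recombination genes, 0.084 for G2/M genes, 0.079 for glycolysis and hypoxia genes and 0.067 for ribosome biogenesis genes.

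Between WT cells of RS4:11 and Nalm6 3177 genes responded differently. The medians, RS4:11 minus Nalm6, were 0.691 for NF-kB genes, 0.414 for histone genes, 0.337 for ribosome biogenesis genes, -0.284 for precursor B cell genes, 0.267 for the stress response list, 0.221 for the senescence and lymphoid activation list, 0.204 for G2/M genes, 0.162 for glutathione and efflux genes, 0.129 for cholesterol biosynthesis genes and -0.117 for p53 targets. For each pair of lines the single genes examined were those named in the WT comparison of either line, so other genes with differences as large are not listed here. Of these 73 genes, 20 differences between lines were 1 log2 unit or more in size, and 89 smaller ones also passed. TNFAIP3 (1.732) and RELB (1.087) responded more in RS4:11 than in Nalm6, whereas BBC3 stood at -1.482, CDKN1A at -1.238 and SESN1 at -1.041.

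REH and Nalm6 differed in the response of 1113 genes, with a median of 0.448 for p53 targets and a difference of -1.38 for HIST1H1T. REH and RS4:11 differed in 4059 genes. The medians, REH minus RS4:11, were -0.72 for NF-kB genes, -0.708 for histone genes, 0.517 for p53 targets, -0.378 for ribosome biogenesis genes, -0.326 for the stress response list, -0.267 for glycolysis and hypoxia genes, -0.242 for heat shock and immediate early genes, -0.193 for cholesterol biosynthesis genes, -0.137 for the senescence and lymphoid activation list, 0.121 for interferon-stimulated genes and 0.111 for precursor B cell genes. Of the genes examined, those that responded more in REH than in RS4:11 were PURPL (1.815), APOBEC3H (1.603), ITGAM (1.059), TRIM22 (1.05), BBC3 (1.031) and PHLDA3 (1.014). Those that responded less, or fell more, were BIRC3 (-3.9), JUN (-2.001), TNFAIP3 (-1.913), RELB (-1.867), HIST1H1T (-1.432), HIST1H2AD (-1.337), IKZF3 (-1.047) and ASNS (-1.045). For REH the line and a possible library batch cannot be told apart.

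The smaller p53 response in KO cells was weighed against 3 explanations. Scaling of the libraries is argued against, since with RLE factors or protein-coding genes alone each line kept at least 95.3% of its median difference, and less CD22 transcript in the KO cells cannot be the whole cause, since in Nalm6 the lower 95% bound of the KO minus WT difference was -0.073. A response scaled down alike for all genes is argued against in RS4:11, where the KO over WT ratio of the NF-kB list exceeded that of the p53 list by at least 0.889 with any library left out. Some lists did shrink there, at 0.71 for E2F targets and 0.743 for histone genes beside 0.326 for p53 targets. Others did not, such as NF-kB (1.294) and ribosome biogenesis genes (1.044). The NF-kB list lay lower in RS4:11 KO control cells (median -0.209), and BIRC3 rose by 8.56 CPM in KO against 11.1 in WT. A smaller response of many genes, uneven between lists, thus stays open in RS4:11. In Nalm6 and REH a generally smaller response also stays open, since other lists shrank to a like degree or more. There the KO over WT ratio of the mean response was 0.769 and 0.729 for p53 targets, 0.527 and 0.356 for histone genes and 0.777 and 0.454 for E2F targets. Loss of DNTT itself, a difference between KO and WT clones and the amount of drug that reached the DNA may each lie behind the pattern, as may other differences between the KO and WT cells, and they were not separated by any test here.

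The large number of genes that differed between KO and WT control cells was weighed against copy number and library size. Called genes inside 10 Mb windows with a median of at least 0.3 in size made up at most 4.18% of the called genes of a line. Most called genes thus lie outside windows shifted on that scale. The test counts only genes inside the windows, so it does not bear on effects of such regions on genes elsewhere. With the libraries of each line thinned to its lowest total, the lowest ratio of the new to the full count was 0.879. An effect of DNTT and differences between separately grown or cloned cells may both contribute, and no test here separates them.

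The rise of NF-kB genes in RS4:11 was weighed against a single library and against myeloid cells. Without each RS4:11 library in turn the highest camera adjusted p in WT or KO was 1.85e-71, which argues against a single library. Monocytes, macrophages or granulocytes in the InO libraries are argued against, since S100A8 and S100A9, abundant in such cells, had 0 counts in each RS4:11 group and the highest rise that the data allow for LYZ or either of them was 0.511% of the rise of BIRC3 in CPM. CSF1R stood at 9.71 CPM with InO against 8.02 in control in WT (edgeR adjusted p = 7.87e-02) and at 5.48 against 4.5 in KO. Other cell types, whose marker lists were not called higher or had fewer than 5 tested members, stay open, as does a response that belongs to this line, which was not tested apart from them.

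Other splits of the same libraries were fitted to ask whether chance could give as many genes. Each of 6 comparisons of 3 libraries with 3 has 10 splits, which are too few for a share under 0.05, and the real split was the 1 with the most genes in each. Nalm6 WT with InO gave 4695 genes against at most 6 in another split. The real counts were 1621 in Nalm6 KO with InO, 5962 in Nalm6 control cells, 2971 in RS4:11 WT with InO, 5640 in RS4:11 control cells and 2253 in REH KO with InO, and the highest of the other splits was 0 in each. For the difference between RS4:11 and Nalm6, 1 of 22 drawn splits gave as many genes, the real one with 3177 against a highest other of 2733. That share is just under 0.05 only because 22 splits were drawn, and it is the smallest they can give. None of the drawn splits exchanged all InO libraries of a single line and left the other line whole. The test therefore does not exclude chance. In 9 of the other splits one line kept or exchanged its groups whole and so carried its InO response, and these called 1314 to 2733 genes, while the 12 that mixed the groups of both lines called at most 0.

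For the Nalm6 interaction 5 of 100 drawn splits, the real one included, gave at least the real 224 genes, so this test does not exclude chance. A smaller first draw had been seen before 100 were drawn. The highest of the other splits called 7510 genes, many times the real count, which points to a structure of the samples: the 4 other splits with as many genes all exchanged 0 or 3 KO libraries in one treatment and so carry the difference between KO and WT itself. The 77 splits that exchanged 1 or 2 KO libraries in each treatment called at most 0 genes. In 5 simulations per line with equal responses in both genotypes the interaction called at most 1 gene in Nalm6, 1 in RS4:11 and 0 in REH. Each gene was drawn independently there, so a shift shared by the libraries of a group could not occur. The simulations therefore do not bear on such a shift.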

How the results depend on the processing

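Counting protein-coding genes only was an alternative chosen after the data had been seen. Of the recomputed counts of called genes 232 stayed within 1.5 times of the count reported and 38 moved further. No named gene changed sign under any alternative, and of 228 named values 224 kept their call under each, the exceptions being DNTT in both Nalm6 comparisons with InO, HIST1H4D in the Nalm6 interaction and CD22 in RS4:11 WT, which also failed with only its 2 groups fitted (adjusted p = 6.44e-02). Genes whose call or size rested on a single library had mostly been left out beforehand, so these figures do not measure how stable calls are. The 215 recomputed scores kept their direction and side of the threshold. Of the called lists 69 were lost with an estimated correlation and 2 with fry, homologous recombination genes in the Nalm6 interaction (1.85e-01) and G2/M genes between REH and Nalm6 (7.91e-02). The median change of all genes lay between -0.03 and 0.039 under each setting. Leaving out libraries leaves 1 in some groups, which is then assumed to vary like the rest. Smaller interactions can be missed: of simulated changes of 0.5 on the log2 scale 58.2% were recovered in RS4:11.

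DESeq2 called 486 genes for the interaction in Nalm6 and 182 in RS4:11. Without a filter these were 667 and 723, where genes of low count enter the fit. One fit of all 34 libraries gave 2045 genes for RS4:11 KO with InO, 343 for its interaction, 1242 for REH KO with InO and 594 for the REH interaction. The cause was not tested. At an adjusted p of 0.01 all 30 overlaps of calls between comparisons of InO with control fell by more than 1.5 times, for example from 774 higher and 585 lower genes shared by WT and KO of Nalm6 to 420 and 328, since fewer genes are called, and each stayed above its value for independent lists. The share of higher genes moved from 17.5% to 30.2% with DESeq2, 55.2% without a filter and 44.9% in the joint fit for the RS4:11 interaction, from 37.1% to 53.3% with DESeq2 for Nalm6, from 56.2% to 44.7% without a filter for Nalm6 KO with InO, from 48.4% to 59.1% likewise for RS4:11 KO, and from 51.1% to 32.1% without a filter and 62.1% with protein-coding genes between REH and Nalm6.

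With each library left out in turn, counts ran from 1057 to 1558 for Nalm6 KO with InO, 115 to 751 for the Nalm6 interaction, 401 to 972 for RS4:11 KO with InO, 51 to 158 for the RS4:11 interaction, 1409 to 2026 for REH KO with InO, 501 to 2228 for the REH interaction, 2993 to 4358 for REH control cells, 493 to 1566 between REH and Nalm6 and 2660 to 4254 between REH and RS4:11. In that order, the lowest came without KO control replicate 1, WT InO replicate 2, KO InO replicate 1, KO InO replicate 3, KO control replicate 1 and, for the comparisons after these, REH WT control replicate 3. The highest that moved by over 1.5 times came without WT InO replicate 3 in both Nalm6 (751) and RS4:11 (158) and without KO InO replicate 3 in REH (2228). Fewer libraries account for a lower count by construction, and the cause of the higher ones was not tested.

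With the replicate number as a replicate block the REH interaction gave 2063 genes, Nalm6 160 and RS4:11 71, and REH KO with InO gave 2964. Libraries of equal number deviated together, with a correlation over 0.1, in 5 of 18 pairs in Nalm6, 4 of 15 in RS4:11 and 11 of 15 in REH. In REH the median was 0.178 for equal and -0.1 for unequal numbers, and the lowest value for equal numbers was -0.328. Not every pair of a line exceeded 0.1, so the numbers were not taken to pair the samples in any line, and the REH values are a hint from the data, not the design, that some libraries of equal number share more than their group.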

Other observations

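The tests of copy number reported here were chosen before their results were seen, and the genes in this part were chosen after their values were seen. In control cells several genes of B-cell development differed between KO and WT. RAG1, which cuts antigen receptor genes at the step before DNTT acts, was higher in Nalm6 KO by 0.94 on the log2 scale (SE 0.03, edgeR adjusted p = 5.15e-14) and lower in RS4:11 KO, at -0.40 (SE 0.04, edgeR adjusted p = 7.22e-07). In RS4:11 KO 15 of 31 precursor B cell genes were lower and 3 higher, and the list was not called with an estimated correlation (adjusted p = 4.24e-01). The adaptor gene BLNK differed by -1.72 and TCL1A by -1.01 there, whereas IL7R was higher by 0.67. The myeloid surface gene CD33 was higher in RS4:11 KO by 2.10 (7.86 against 1.83 CPM), while CSF1R differed by -0.83.

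The heat shock and immediate early list was not called between KO and WT control cells (camera adjusted p = 9.08e-01 in Nalm6, 2.38e-01 in RS4:11 and 4.68e-01 in REH), while single genes inside and outside it differed. The heat shock gene HSPA1A had 10 counts in RS4:11 KO control against 1835 in WT, a log2 ratio of -7.33 with a counting interval of -8.39 to -6.45, and it has a nearly identical copy with which reads can be shared. In REH KO the small heat shock gene HSPB1 differed by -1.66 and PROM1, the stem cell antigen CD133, by -1.68, while the cystine transporter SLC7A11 was higher by 0.90 and the anti-apoptotic BCL2 by 0.61. MX2, an interferon-induced gene, was lower in KO control cells of each line, at -1.78 in Nalm6, -1.35 in RS4:11 and -0.96 in REH, and LGALS1, which encodes galectin-1, at -1.21, -1.41 and -0.77.

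The blocks of neighbouring genes in Nalm6 and RS4:11 may reflect copy number differences between the KO and WT cells. If so, the same genes should differ in the InO libraries, which had not been used to find the blocks. On chromosome 21 in Nalm6 the median log2 difference, KO minus WT, was -0.407 with InO, beside -0.405 in control, with 97 of 140 genes called lower and 7 higher. In the first 50 Mb of chromosome 8 in RS4:11 it was 0.905 with InO and 0.88 in control, and 92.7% of 151 genes lay above 0 with InO. Both values are those a copy number difference needs, DNA was not measured, and the control and InO libraries come from the same cells, so a regional change of expression that the cells carry in both conditions could give them too.

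Several of the most changed genes of RS4:11 KO control cells lie on chromosome 7 (GRCh38). DYNC1I1 (95772506 to 96110322) was higher by 5.26 and its neighbour SLC25A13 (96120220 to 96322147) by 2.83. RUNDC3B (87627548 to 87832296) had 1 count in KO against 2391 in WT, a log2 ratio of -11.03 with a counting interval of -16.34 to -8.56. MEST (130486171 to 130506465), an imprinted gene, had 15 against 16476, at -9.91 with an interval of -10.75 to -9.19, and TES (116210493 to 116258783) had 0 against 5309. The window from 80 to 90 Mb had a median of 0.321 and that from 150 to 160 Mb one of -0.354. On chromosome 4 the windows between 160 and 180 Mb lay at -0.306 and -0.382. No explanation of these values was tested.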
